A study of Oryza sativa and Arabidopsis thaliana with 28 samples.

How the data were processed

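The series holds 28 samples of Arabidopsis and rice. The comparisons used 4 ac4C-seq libraries (1 treated and 1 control per species) and 12 RNC-seq libraries (2 each of mRNA and RNC for Arabidopsis, rice WT, genotype Kitaake, and osnat10-1, called osnat10 here). The other 12 samples, antibody pulldown (acRIP) of ac4C with IgG and input, were not analysed here. Per the submitters' processing notes, reads were handled with STAR 2.5.3a and SAMtools, with the builds TAIR10 and IRGSP-1.0; the step each tool served and the rule for listing sites are not stated.

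The deposited site tables give a count of T reads and a count of reads per library at reference cytosines. The second count, though headed C, was taken as all reads at the position, because the deposited p-value equals a 2-proportion test on it at 100% of sites (relative tolerance 0.001). The deposited adjusted p-value equals the Benjamini-Yekutieli adjustment at 100% of sites (same tolerance). The RNC tables hold RPKM made by the authors, and TE deposited as the natural log of mean RNC RPKM over mean mRNA RPKM (100% of Arabidopsis transcripts, tolerance 1e-06). Arabidopsis mRNA values are whole reads over the span of the gene (100%, tolerance 0.01 reads). The RNC values of a gene's transcripts share a read count but differ in the length divided by; 8362 of 9065 genes with several transcripts had more than 1 RNC value, and their mean was used. The source of these lengths is not stated. RNC reads were recovered for 21172 of 21174 genes from the ratios of the values between libraries and transcripts. Tested on simulated data, 89.3% of genes were recovered exactly and 96.3% within 2-fold; the rest can be a whole-number fraction of the true reads. The rice table lists 3695 genes that the authors called ac4C-modified. Its WT columns share names, so the libraries are called first and later listed.

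Sites with at least 10 reads in both libraries were tested with a two-sided Fisher's exact test on T and other reads. The p-values came from a function written for the purpose, checked against scipy 1.17.1 on simulated sites. After the Benjamini-Hochberg adjustment, sites were called at an adjusted p under 0.05 with the higher rate in the treated library. Intervals are 95% Clopper-Pearson (exact) intervals. The limit for a count of 0 uses 3 counts. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Sites carry no strand; reference cytosines were assigned to plus-strand genes of the RNC tables. With 200 sites raised by 1 or 3 points in simulated data, 53% and 83% were called in Arabidopsis (2 unchanged sites called) and 15% and 54% in rice (0 unchanged).

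RPKM plus 1 on the log2 scale was tested with limma 3.58.1 (eBayes with trend, R 4.3.3) over genes with a mean of at least 1, without further scaling and without a block, with the Benjamini-Hochberg adjustment. The 4 rice groups shared a fit, and TE in osnat10 is the interaction term. Simulated 2-fold and 4-fold changes in 200 genes were found at 67% and 97% in Arabidopsis (1 unchanged gene called) and at 5% and 49% for rice TE (3 unchanged genes called). P-values from 2 libraries per group cover only the spread between these libraries, and the labels call only the acRIP replicates biological. Gene lists were tested with camera (preset correlation 0.01, then estimated) and fry for lists with at least 5 tested members. Camera compares a list with the other genes. Fry asks whether a list's genes move one way; its direction was Up where camera was Down for cytosolic ribosomal proteins (fry adjusted p = 0.00252), light harvesting (0.00252), mitochondria-encoded genes (0.00437) and genes with upstream reading frames (0.00252). Genes with a site were set against 10000 random lists matched in 50 bins of expression (seed 11). Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0, edgeR 4.0.16 and matplotlib 3.10.9.

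The tests, lists, thresholds and most alternatives were chosen before the data were examined. Named genes were the 12 largest called changes per direction with a symbol and the same sign in both replicates, up to 4 members per list with the smallest adjusted p, the acetyltransferase genes, and for sites the 12 highest treated rates at 50 or more reads, 1 per gene or, outside genes, 1 per 10 kilobases. Exceptions chosen after values were seen were the further rRNA bases, the rice rRNA-sized genes, atpA, atpH and the largest changes among genes without a symbol. The reference name table covers rice only, and 0 of 3695 rice IDs matched it, so rice lists were not tested, few rice IDs are given, and the gene mutated in osnat10 was not identified in the table. Arabidopsis symbols and codes were paired in lists written from general knowledge. AT1G10490, the other Arabidopsis acetyltransferase gene, is not in the table. Codon position and sequence context of sites need a genome and were not computed.

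Alternatives covered site coverage, stricter site thresholds, pseudocount 0.1, filters at 0 and 5, median centring, quantile normalization, a replicate block and leaving out each library. Added after seeing the data were recovered reads (limma and edgeR quasi-likelihood), the lowest and highest RNC value of a gene, nuclear sites only, the deposited adjusted p, the second count as unconverted reads, plus-strand genes only (also for the matched lists), genes with sites of at least 5 points, scaling of the gene lists, centring of the median TE shift, rice without genes at 0, and an unadjusted p under 5e-10.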

Results

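The series measured N4-acetylcytidine (ac4C), a modified cytidine made by RNA cytidine acetyltransferases, together with the association of mRNAs with ribosomes, in Arabidopsis (Col-0) and rice (japonica) seedlings. In ac4C-seq, RNA is reduced with NaCNBH3 so that ac4C is read as T, and C-to-T rates are set against a control library. There was 1 treated and 1 control library per species, from 10-day-old Arabidopsis and 15-day-old rice (cultivar Nipponbare), both with 20 min of treatment and with no replicates. In RNC-seq, mRNA bound to ribosome-nascent chain complexes (RNC) was compared with input mRNA, with 2 libraries per group in Arabidopsis and in rice wild type (WT, genotype Kitaake) and osnat10-1 (osnat10 below), a rice mutant line named after an RNA cytidine acetyltransferase gene. The median depth at the tested sites was 788 treated and 2795 control reads in Arabidopsis, and 801 and 725 reads in rice. The Arabidopsis mRNA libraries held 39128550 and 39339118 reads by the step size of their values. Over the genes of the table, mRNA reads came to 18768358 and 18847446 and recovered RNC reads to 20330956 and 18847216. For rice the read depth of the RNC and mRNA libraries is unknown. Their median RPKM was 24.7 and 24.7 (WT RNC), 17.42 and 18.56 (WT mRNA), 21.3 and 23.1 (osnat10 RNC), and 16.33 and 17.65 (osnat10 mRNA). Positions are those of TAIR10 and IRGSP-1.0. Symbols of Arabidopsis genes come from gene lists written with their codes before the data were examined and were not checked against an annotation, since the deposited table gives codes only.

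The first question was where RNA carried more C-to-T reads after reduction. In Arabidopsis, the 18S rRNA gene AT3G41768 (chromosome 3, 14197677 to 14199484) held the deepest of the called sites with a rate of 50% or more, and low-rate sites lay in nearly every plus-strand member of the lists for photosynthesis, ribosomal proteins and chloroplast-encoded genes. At 63083 of 66873 tested sites (94.3%) the treated library had the higher rate and 317 had the lower one (two-sided Fisher's exact test, adjusted p under 0.05). The median rate was 1.14% in the treated and 0 in the control library. The test compares these 2 libraries, not the conditions, and every listed site had at least 5 treated T reads, so sites without treated T reads were never listed. Of the called sites, 2688 reached a treated rate of 5%, 528 reached 10%, 17 reached 50% and 0 reached 90%. At the 4389 sites with at least 20000 treated reads, the medians were 0.816% and 0.0287%. Mitochondrial sites were called at 170 of 425 positions and chloroplast sites at 4224 of 4702.

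The 18S rRNA is a known carrier of ac4C. At base 1284 of AT3G41768, counted from the gene start (position 14198960), 53711 of 73685 treated reads were T, or 72.9% (95% Clopper-Pearson interval 72.6 to 73.2), against 528 of 91123 control reads, or 0.579% (0.531 to 0.631). The median over the 391 listed sites of this gene was 0.937% treated and 0.0325% control. Base 1152 of the same gene (position 14198828) had 11.7% (11.2 to 12.2) against 0.765% (0.655 to 0.889), and base 182 (position 14197858) had 0.950% (0.889 to 1.01) against 0.0157%. In AT2G01010 (chromosome 2, 3706 to 5513), the other listed 18S rRNA gene, base 1284 (position 4989) had 11.7% (11.1 to 12.2) against 0.563% (0.454 to 0.690), and base 182 (position 3887) had 19.4% (18.5 to 20.4) against 0.367% (0.168 to 0.696), while base 1152 (position 4857) had 0.735% (0.640 to 0.841) against 0.0370%. The copies thus disagreed widely at each of these bases. Both genes are 1808 bases long, and reads of near-identical copies cannot be assigned to one of them with certainty. These bases were chosen after their values were seen, except for position 14198960, which the rule for the highest rates named.

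**Figure D1:**
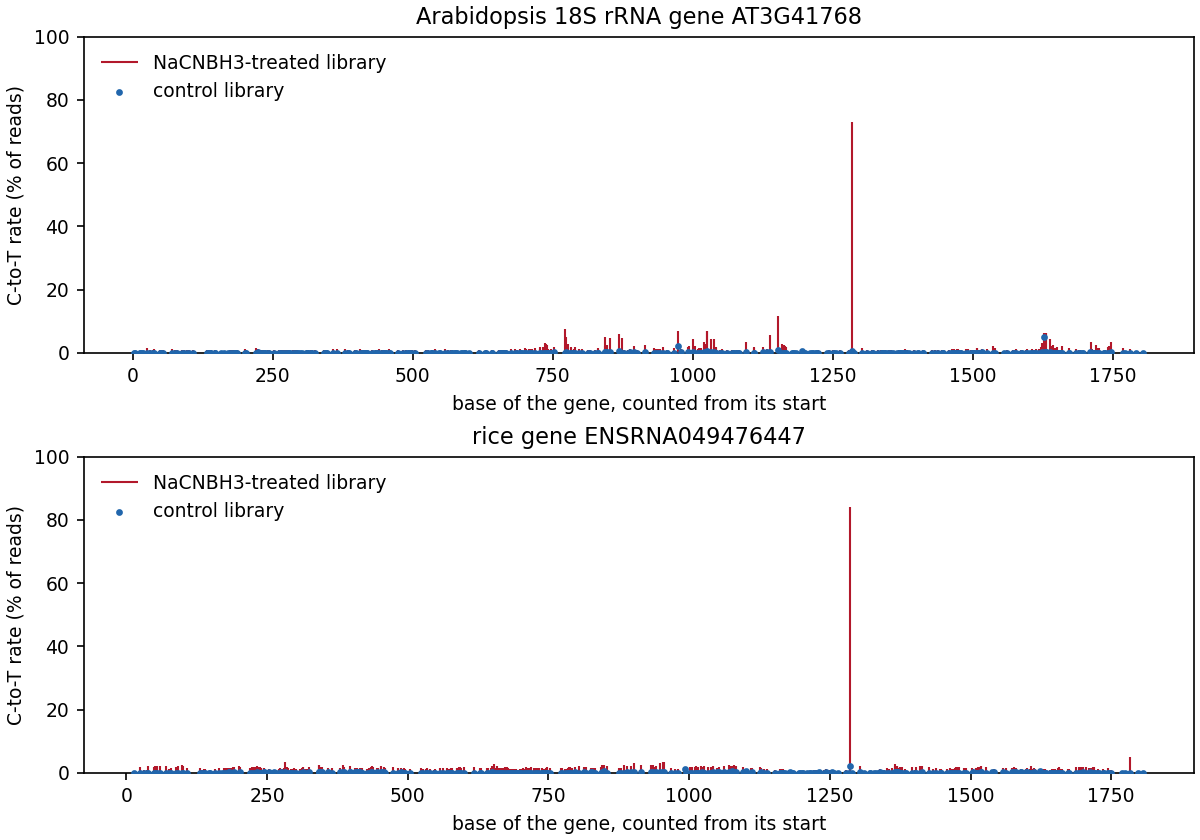
C-to-T rate (% of reads) at each listed cytosine of the Arabidopsis 18S rRNA gene AT3G41768 and the rice gene ENSRNA049476447, by base of the gene; red lines are the treated library and blue points the control library, 1 library each. The tallest line is base 1284 in Arabidopsis (72.9%) and base 1285 in rice (84.1%).

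All 20 plus-strand members of the light harvesting and Calvin cycle list had a called site, as did 24 of 25 cytosolic ribosomal protein genes, 33 of 34 chloroplast-encoded genes and 7 of 9 translation factors. Random lists of nuclear genes matched on mRNA level held a median of 18, 21, 10 and 6 such members. This placed the lists at percentiles 93.0, 98.4, 100 and 74.4 of 10000 matched lists. The lists were not matched on ac4C-seq depth. Their called sites had a median treated depth of 3295, 794, 4247 and 3059 reads, against 784 over all called sites. The percentiles therefore cannot tell a property of a list from read depth. Rates in these groups were low: the median over called sites was 0.929% against 0.0276% for light harvesting, 1.09% against 0 for ribosomal proteins and 0.734% against 0.0168% for chloroplast-encoded genes. Translation factors held sites of at least 5 points above control in 4 members, against a median of 1 in matched lists (percentile 98.5), while the other lists held few: 0 members for light harvesting (percentile 6.835), 2 for ribosomal proteins (26.0) and 2 for chloroplast-encoded genes (17.96). Of the translation factors, EEF1A2 (AT1G07930, chromosome 1, position 2460020) and EEF1A1 (AT1G07920, position 2456695), elongation factors, had 40.9% (39.3 to 42.5) against 26.7% and 25.7% (24.8 to 26.6) against 16.2%. The initiation factor EIF4G (AT3G60240, chromosome 3, position 22262689) had 7.55% (3.31 to 14.3; 8 of 106 reads) against 0 of 240, which allows up to 1.25%. PAB4 (AT2G23350, chromosome 2, position 9945626), a poly(A)-binding protein gene, had 5.48% (2.40 to 10.5; 8 of 146 reads) against 0 of 383, which allows up to 0.783%. The elongation factor sites had high control rates, so T reads there were not specific to the treated library. The chloroplast-encoded members with sites of at least 5 points, ATCG00300 and ATCG00500, also had control T reads (16.6% and 3.65%).

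Other lists held fewer sites. The chaperone HSP90.2 (AT5G56030) reached 22.3% (18.18 to 26.89) against 9.48% and was the only heat shock gene with a site among 3. Genes with conserved upstream reading frames had a site in 3 of 6 members (percentile 32.1), cold and ABA response genes in 2 of 6 (38.2) and mitochondria-encoded genes in 3 of 22 (76.3). Core histones had sites in 1 of 3, cellulose synthases in 1 of 2, the flavonoid pathway in 1 of 4, root markers in 0 of 3, and the acetyltransferase gene ACYR2 (AT3G57940) had none. Over all plus-strand genes, 3610 of 10620 (34.0%) held a called site, with a median of 3. Their median mRNA level was 7.53 RPKM against 1.34 for the rest, and the share was 2.82% among the lowest 10% of genes by expression and 84.8% among the highest 10%. Spearman's rho across genes between mRNA level and number of called sites was 0.616, and genes are not independent replicates.

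Of the 12 Arabidopsis sites with the highest treated rates at 50 or more reads, most were also high in the control. Position 10372913 of chromosome 5 had 87.7% (81.6 to 92.3) against 91.4% (not called), and AT4G11310 had 70.4% (65.2 to 75.2) against 60.4%. Besides the 18S site, chromosome 4 position 3058694 (77.7%, 73.5 to 81.6, against 1 of 22 reads) and chromosome 5 position 21990716 (69.1%, 66.4 to 71.7, against 9.39%) stood in no gene of the RNC table. AT3G49110 had 65.9% (61.0 to 70.4) against 24.9% at position 18202750, and AT3G16410 had 62.7% (59.2 to 66.1) against 36.2% at position 5574272.

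In rice, 18S-sized genes held converted sites as well. In ENSRNA049476447 (chromosome 9, 27410 to 29220, 1811 bases), base 1285 (position 28694) had 84.1% (83.9 to 84.4; 79261 of 94212 reads) against 2.14% (2.06 to 2.24). The median over its 414 listed sites was 1.47% against 0.0661%, and base 1784 had 4.95% (4.53 to 5.39; 495 of 10003 reads) against 0.0353%. In ENSRNA049476430 (chromosome 9, 3626 to 5436), base 1285 had 68.6% (68.1 to 69.0) against 0.0624% (0.0479 to 0.0800), and base 1784 had 24.0% (21.7 to 26.4; 321 of 1337 reads) against 0.292% (0.179 to 0.451). In ENSRNA049471102 (chromosome 2, 28719357 to 28721167), base 1285 had 9.66% (8.42 to 11.02; 199 of 2059 reads) against 0 of 5313 reads, which allows a rate of up to 0.0565%. These genes and bases were taken up after their values were seen, except for position 28694, which the rule for the highest rates named; the file gives the genes no name, and copies share reads as above. Among protein-coding genes, Os07g0529600 (chromosome 7, position 20724692) had 94.6% (94.0 to 95.2; 4908 of 5188 reads) against 0 of 3258, which allows up to 0.0921%. Chromosome 6 position 21380115, in no listed gene, had 88.3% (85.8 to 90.6; 659 of 746 reads) against 0 of 27, which allows up to 11.1%. Both sites rest on 1 treated and 1 control library, so acetylation cannot be told from another difference between these libraries. Of the 12 rice sites with the highest treated rates at 50 or more reads, most were also high in the control. Chromosome 1 position 34919352 had 95.8% against 99.2% (not called), and mitochondrial position 29261 had 91.9% against 85.9% (called).

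Over the whole rice list, 203979 of 341377 tested sites (59.8%) were called higher and 1002 lower. The median rate was 1.102% treated and 0 in the control, and 2288 called sites reached 5%, 856 reached 10%, 58 reached 50% and 2 reached 90%. Listed sites covered chromosomes 1 to 8, the first 30801 bases of chromosome 9, and both organelles. Within those stretches, 1477 of 1574 plus-strand genes of the table (93.8%) held a called site, with a median of 39. The table holds the authors' ac4C genes alone, so this share is not independent evidence. Their median WT mRNA level was 19.3 RPKM, against 7.63 for the 97 genes without. With the deposited adjusted p, which comes from another test and another adjustment, the count was 114143 in rice and 55765 in Arabidopsis.

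The next comparison, RNC against mRNA in Arabidopsis, asks how far ribosome-bound levels depart from transcript levels (translation efficiency, TE). In the deposited values, mRNAs of most translation factors and of several ribosomal proteins stood higher in RNC, as did most genes. As a list, translation factors were not called against the other genes (camera adjusted p = 0.144). Most chloroplast-encoded genes and single histone and photosystem mRNAs stood lower. Of 16487 tested genes, 12547 were higher and 2156 lower in RNC (limma on log2 of RPKM plus 1, adjusted p under 0.05), with a median change of 0.98. Centred on the library medians, 6379 were higher and 7216 lower. These values carry a property that bears on every gene below. The length by which the RNC values were divided was unrelated to the span of the gene (Spearman's rho across genes 0.0256), while mRNA values were divided by that span. With RNC reads recovered from the values and divided by the gene's own span, an alternative chosen after seeing the data, 3103 genes were higher and 3498 lower. Changes are given below as deposited, then centred, then from recovered reads, since many had opposite signs.

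The poly(A)-binding protein mRNA PAB2 (AT4G34110) went from 62.1 ± 3.77 RPKM in mRNA to 499 ± 20.3 in RNC (SD, n = 2), a log2 change of 2.99 (SE 0.05) as deposited, 1.94 centred and 0.22 from reads. The ribosomal protein mRNAs RPL10C (AT1G66580; 55.7 ± 1.38 to 496 ± 17.1 RPKM), RPS20B (AT3G47370) and RPL8A (AT2G18020) had 3.13, 2.92 and 2.24 as deposited, 2.08, 1.87 and 1.19 centred, and 0.13, 0.38 and 0.25 from reads. The elongation factor mRNA EEF1A3 (AT1G07940) had 2.45, 1.40 and 0.30. Other members were lower from reads. The initiation factor EIF4G had 2.87 and 1.82 but -0.74 from reads (limma adjusted p = 0.00113). The elongation factor LOS1 (AT1G56070) had 2.84 and 1.79 but -0.28 (limma adjusted p = 0.00230). The ribosomal protein RPL4A (AT3G09630) had 2.85 and 1.81 but -0.96 (limma adjusted p = 2.68e-06). These p-values do not cover errors in the recovered reads, which can be a whole-number fraction of the true reads. PAB4 had 2.69 and 1.64 and was not called from reads (-0.03, adjusted p = 0.685). SAC51 (AT5G64340), a transcription factor with conserved upstream reading frames, had 3.399 as deposited (10.4 ± 0.160 to 119 ± 8.77 RPKM) and was not called from reads (-0.07, adjusted p = 0.522). ACYR2, an RNA cytidine acetyltransferase, was at 0.599 ± 0.0715 RPKM in mRNA and 7.11 ± 0.708 in RNC (2.34, 1.29 centred, and -0.14 from reads, adjusted p = 0.375). The secondary-wall cellulose synthase CESA4 (AT5G44030) had 2.42, 1.38 and, from reads, -0.30 (adjusted p = 0.0996).

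Lower in RNC as deposited, centred and from reads were GAPB (AT1G42970), a Calvin cycle enzyme subunit, the photosystem antenna genes LHCA4 (AT3G47470) and LHCB1.1 (AT1G29920), the histone gene H3.1 AT5G65360, RPS18A (AT1G22780), and BZIP44 (AT1G75390), a transcription factor with an upstream reading frame. GAPB went from 532 ± 4.84 to 136 ± 2.19 RPKM (-1.96 deposited, -3.01 centred, -3.12 from reads), LHCA4 from 2744 ± 54.1 to 851 ± 6.12 (-1.69, -2.74, -0.31) and LHCB1.1 from 4117 ± 89.3 to 1856 ± 47.2 (-1.15, -2.20, -0.72). H3.1 AT5G65360 had -2.21, -3.25 and -0.49, RPS18A -1.41, -2.46 and -0.17, and BZIP44 -1.03, -2.08 and -0.99. The photosystem I subunits PSAO (AT1G08380; -1.25, -2.30, 0.71) and PSAG (AT1G55670; -1.21, -2.25, 0.18), RPL27AB (AT1G23290; -1.63, -2.68, 0.21), RD22 (AT5G25610, a dehydration-response gene; -1.27, -2.31, 0.03), the H3.1 gene AT3G27360 (-1.24, -2.29, 0.59) and HIS4 AT3G45930 (-1.45, -2.50, 0.34) were lower as deposited and not from reads. The largest deposited changes of all were AT5G44180 (9.05; 0.09 from reads) and AT1G64633 (-8.08; -2.16 from reads), which no list names. The table gives AT1G64633 a span from 24019584 to 24019586, with 24 and 22 mRNA reads and 6 and 5 RNC reads, so its value rests on few reads over a few bases. Recovered reads can be a whole-number fraction of the true reads, and then lie at least 2-fold too low. Falls from reads such as those of GAPB, BZIP44, LHCB1.1, EIF4G and RPL4A are therefore uncertain.

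By group, chloroplast-encoded genes were lower in RNC at 25 of 41 tested and higher at 12 (median -0.76). The camera adjusted p of this list was 1.03e-10 with a preset correlation and 0.367 with an estimated correlation. Centred, 31 were lower and 4 higher, while from reads 8 were lower and 17 higher (median 0.11). Examples were ATCG00470 (-1.75 deposited, -2.80 centred, 0.55 from reads) and ATCG00020 (2.36, 1.31, -0.30). Core histones, which package DNA, were higher at 6 and lower at 5 of 14 (median -0.10; camera Down, adjusted p = 0.0045, and adjusted p = 0.554 with an estimated correlation). Centred, 12 were lower; from reads, 13 were higher and 1 lower (median 0.42, camera Up, adjusted p = 2.64e-05, and adjusted p = 0.432 with an estimated correlation). Fry's test of direction called neither list with the deposited values (Down, fry adjusted p = 0.0584 for chloroplast-encoded genes and 0.0646 for core histones). Counts adjusted over the list alone were the same for every list with the deposited values.

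The other lists had no camera call with the deposited values. Translation factors were higher at 14 and lower at 1 of 16 (median 1.87; adjusted p = 0.144), and 6 each way from reads (0.01). Cytosolic ribosomal proteins were higher at 36 and lower at 14 of 55 (median 0.42; camera Down, adjusted p = 0.385, against a positive median), 15 and 35 centred, and 31 and 9 from reads (median 0.18, mean -0.01, camera Up, adjusted p = 0.00196). Light harvesting and Calvin cycle genes were higher at 28 and lower at 12 of 44 (median 0.36; camera Down, adjusted p = 0.229), 10 and 30 centred, and 24 and 13 from reads (median 0.14, mean -0.02). PRK (AT1G32060), a Calvin cycle kinase, had 2.13, 1.08 centred and 0.33 from reads, and GAPA1 (AT3G26650) had 2.06, 1.01 and -0.37. Mitochondria-encoded genes were higher at 13 and lower at 4 of 20 (median 0.90, camera Down, adjusted p = 0.370). Centred, they were higher at 5 and lower at 9, and from reads at 15 and 1 (median 0.65, camera adjusted p = 2.64e-05). The mitochondria-encoded and chloroplast-encoded lists took every gene code of their genome, so neither was limited to mRNAs. All camera calls from reads had an adjusted p = 0.432 with an estimated correlation.

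Smaller lists were mostly higher in RNC as deposited, with a median near that of all genes. Heat shock genes were higher at all 5 tested (median 1.19), with the chaperone HSC70-1 (AT5G02500) at 1.91, 0.86 centred and -0.08 from reads. Cellulose synthases were higher at 5 of 6 (1.17) and lower at 3 from reads (median -0.38; adjusted p = 0.0188). The flavonoid pathway was higher at 9 of 11 (0.90), and from reads 6 were lower and 0 higher (median -0.30; adjusted p = 0.00747). PAL1 (AT2G37040), the entry enzyme of that pathway, had 1.73, 0.68 and -0.11. Cold and ABA response genes were higher at 9 and lower at 1 of 11 (0.88) and 6 and 1 from reads (median 0.37; adjusted p = 0.0202), with the dehydrin RAB18 (AT5G66400) at 2.03, 0.98 and 0.50. Genes with upstream reading frames were higher at 6 and lower at 3 of 10 (median 0.91; camera Down, adjusted p = 0.622), 5 and 5 centred, and 1 and 5 from reads (median -0.22). Both root markers, SCR and SHR, and both 18S rRNA genes were higher as deposited, and AT3G41768 was at -0.12 centred. No microRNA precursor was in the table.

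**Figure D2:**
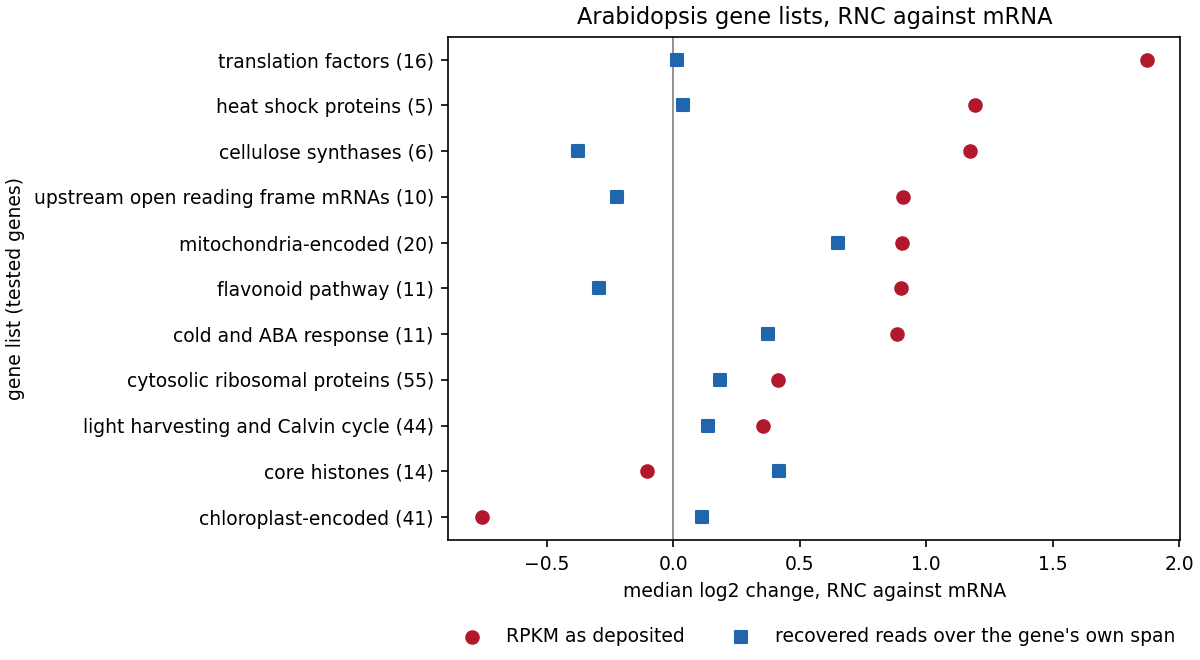
Median log2 change of RNC against mRNA for each Arabidopsis gene list (number of tested genes in brackets); red circles are the RPKM as deposited and blue squares the recovered reads over the gene's own span, each a median over genes from 2 libraries per group. Chloroplast-encoded genes lay at -0.76 and 0.11, and translation factors at 1.87 and 0.01.

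Whether genes with ac4C-seq sites differ in TE was asked next. The 3530 tested genes with a called site had a median change of 1.098, against 0.946 for the 12957 others (limma's camera with a preset correlation, Up, p = 0.0298). The medians were 1.091 against 0.942 in replicate 1 and 1.096 against 0.943 in replicate 2. With pseudocount 0.1 in place of 1 the medians lay closer together, at 1.229 and 1.196 (camera with the preset correlation, p = 0.0279). The camera p was 0.0883 with an estimated correlation and 0.543 among genes with a mean of at least 10 RPKM, where the medians were 1.42 and 1.55. That mean was taken over the mRNA and RNC libraries, so it selects genes partly on the RNC values that enter TE. Chosen after seeing the data, a comparison within plus-strand genes, the only ones that can hold a site here, gave camera p = 0.00142 with the preset correlation (medians 1.098 and 0.874), and genes with sites of at least 5 points gave camera p = 0.00597 with that correlation (1.251 and 0.956). Lists matched on mean expression had higher medians, 95% of them between 1.14 and 1.22, and all 10000 of them exceeded that of the genes with sites (percentile 0), as with lists of plus-strand genes only (95% between 1.14 and 1.19, percentile 0, added after seeing the data), so the tests and the matched lists pointed opposite ways. From recovered reads the median was 0.000189 (percentile 0.44 of matched lists, 95% of which lay between 0.00403 and 0.0235; limma's camera with a preset correlation, Down, p = 0.623). Expression, on which the lists were matched, enters TE itself, so the matched lists cannot settle the direction. Genes are not replicates, and no difference in TE of these genes held under all of these treatments.

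In rice WT, RNC against mRNA gave 1295 genes higher and 380 lower of 3665 tested ac4C genes (limma, adjusted p under 0.05), with a median change of 0.44. Centred on library medians, 728 were higher and 763 lower. All transcripts of a rice gene shared a value in each library. The lengths by which the rice values were divided were not examined. Whether RNC against mRNA in rice depends on them, as in Arabidopsis, is unknown. The chloroplast ATP synthase gene atpA (34210 to 35733), chosen after its values were seen, was lower in RNC (10.3 ± 3.16 RPKM in mRNA, 2.33 ± 2.55 in RNC, SD, n = 2; log2 -1.98, limma adjusted p = 0.0179). The other named organelle genes, atp1, atp6, atpH, cox1 and cox3, were not called. The rice table pairs no names with its other IDs, and 0 of 3695 matched the gene name table, so no rice gene list could be tested and few genes are given by ID.

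The osnat10 line was compared with WT to ask how the levels of these genes differ in the mutant. In mRNA, 44 genes fell and 4 rose of 3665. In RNC, 150 fell and 21 rose (87.7% of those called fell), and 842 genes had an unadjusted p under 0.05. Os03g0807700 (chromosome 3, 33765712 to 33767700) fell in both, from 34.9 ± 2.01 to 1.98 ± 0.188 RPKM in RNC (log2 -3.59, SE 0.28, limma adjusted p = 0.00131) and from 17.0 ± 3.84 to 3.04 ± 0.468 in mRNA (-2.14, adjusted p = 0.00514). Os02g0308400 (chromosome 2, 12113907 to 12114966) fell in RNC, from 43.5 and 33.0 RPKM in the WT libraries to 0 and 6.34 in osnat10 (adjusted p = 0.0232); its mRNA change of -3.01 was not called (adjusted p = 0.119). Os03g0592500 (chromosome 3, 22000043 to 22001240) rose in RNC from 57.7 ± 10.5 to 226 ± 9.60 RPKM (1.97, adjusted p = 0.00517) and in mRNA by 1.59 (adjusted p = 0.0163). Os10g0181600 (chromosome 10, 5592943 to 5595558) rose in RNC from 3.21 ± 2.31 to 12.6 ± 1.38 (1.80, adjusted p = 0.0445), with 0.97 in mRNA (adjusted p = 0.478). The proton channel gene atpH, chosen after its values were seen, had an RNC change of 1.98 (limma adjusted p = 0.0691).

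**Figure D3:**
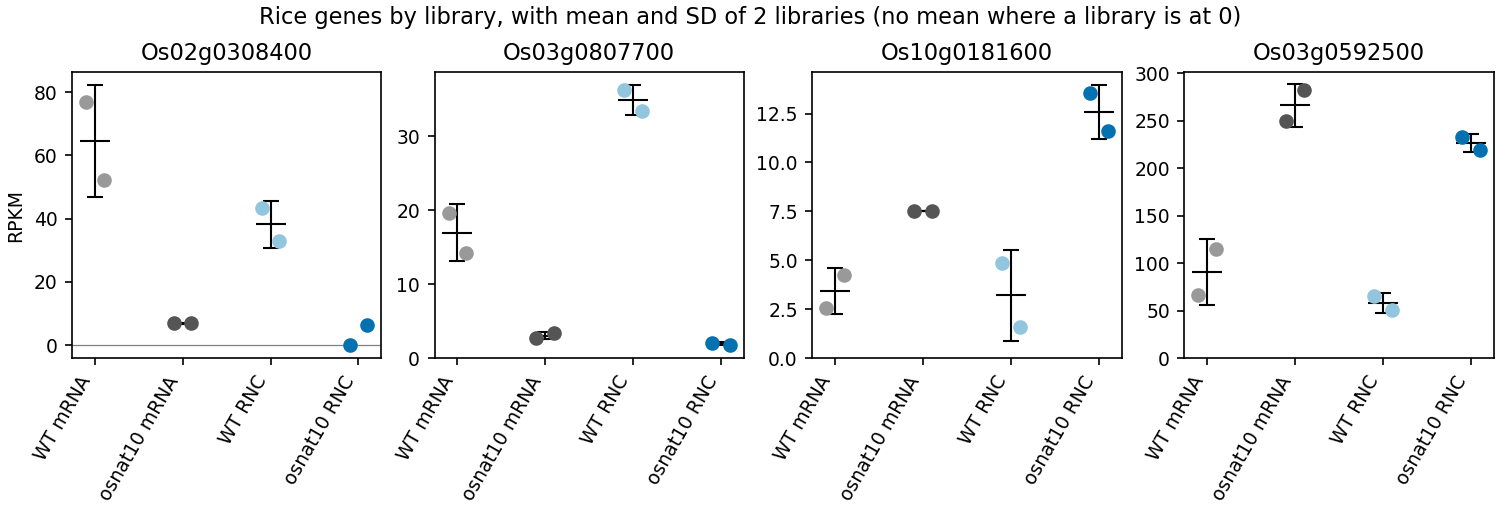
RPKM of the 4 rice genes in each library; points are libraries, bars the mean and SD of 2 libraries, drawn only where no library is at 0. Os03g0807700 falls from 34.9 to 1.98 in RNC, and Os03g0592500 rises from 57.7 to 226.

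Genes lower in both mRNA and RNC numbered 33, and 3 were higher in both. Both contrasts come from the same fit, so no chance number is given. Spearman's rho across genes between the mRNA and RNC changes was 0.389. The counts rested on single libraries. Without osnat10 RNC replicate 2, the RNC count was 611, and without the first or the later listed WT RNC library it was 66 (39 lower, 27 higher) or 49 (45 lower, 4 higher). Without osnat10 mRNA replicate 1 or 2 it was 64 each. The mRNA count of 48 went to 14 and 102 without the first and later listed WT mRNA library, to 13 and 15 without osnat10 mRNA replicates 1 and 2, and to 85 and 86 without osnat10 RNC replicates 1 and 2. Centred on library medians, 76 genes fell and 30 rose in RNC, and 31 fell and 4 rose in mRNA.

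For TE itself, the change of RNC relative to mRNA in osnat10 against WT, limma called 0 genes, and 219 had an unadjusted p under 0.05. Os03g0807700 had the larger TE value of the 2 that fell (-1.45, adjusted p = 0.719). Tested on simulated changes, the fit found 5% of genes with a 2-fold and 49% with a 4-fold change in TE. Changes of 2-fold were thus mostly missed, and those of 4-fold often. Without osnat10 RNC replicate 2 the count was 103, of which 94 were lower in osnat10; it was 2 without the first listed WT RNC library and 1 without osnat10 RNC replicate 1. The median log2 TE over genes was 0.471 and 0.421 in the WT RNC libraries (mean 0.446 ± 0.0352, SD) and 0.307 and 0.401 in osnat10 (0.354 ± 0.0665). The median over genes of the difference was -0.10. The two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. It was -0.03 with centred libraries, -0.15 without the later listed WT mRNA library, -0.04 without osnat10 RNC replicate 1, and -0.17 and -0.04 without osnat10 mRNA replicates 1 and 2.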

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

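The tests of shares and spacing of listed sites and of averaging over transcripts were chosen before their results were seen; those against equal rates, of spacing above background, of RNC lengths, of read ratios and of the rice RNC changes were chosen only after the result was seen.

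Called sites also lay outside the genes that the comparisons used. Their rates lie above the control library by the rule for calling, so the medians below only describe them. In Arabidopsis 6816 called sites lay in no gene of the RNC table (median 0.939% against 0.00852%) and 1363 in minus-strand genes only (1.01% against 0.00602%). In rice 85047 lay in no gene of the table (1.17% against 0), which lists ac4C genes alone, and 774 in minus-strand genes only (0.291% against 0).

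The treated library had the higher rate at nearly all listed sites in both species. Of the sites with at least 5 T reads in both libraries, 93.0% of 11366 in Arabidopsis and 90.23% of 24790 in rice were higher in the treated library. The bound of 60% set beforehand was too low for Arabidopsis. With equal rates, listing on at least 5 treated T reads would itself give 64.2% at the depths of these sites (59.3% in rice). The excess of 28.8 points, and of 30.9 points in rice, argues against listing by that rule as the whole cause, as far as reads are independent. The rule used for listing is not stated, so listing by another rule stays open. Low-rate conversion of most cytosines may account for many deep sites: the spacing of listed sites with at least 20000 treated reads (median of 3 bases in both species) decides nothing, because the control rate alone would give 21.7 and 17.1 T reads at their median depth, but called sites of that depth with a treated rate of at least 0.2% also lay a median of 3 bases apart in Arabidopsis and 3 bases apart in rice. No ac4C-seq library came from an acetyltransferase mutant, so no biological explanation was tested.

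In Arabidopsis, deposited TE varied widely between genes. Averaging over transcripts is argued against, since genes with 1 transcript had an interquartile range of 1.80 on the log2 scale. The length that RNC values were divided by enters deposited TE by construction. Spearman's rho across genes of deposited TE with the inverse of that length over the gene span was 0.865 over 14123 genes, which is partly built in. Over these genes the interquartile range was 1.70 for log2 deposited TE and 0.496 for log2 RNC reads over mRNA reads, where that length is left out. Much of the deposited spread thus went with the length. The ratio of RNC to mRNA reads, which would carry ribosome association, had a rho of 0.210 with deposited TE over all 21172 genes and of 0.148 over the same 14123 genes with at least 200 mRNA reads. Where the lengths come from stays open.

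In rice, most called RNC changes were lower in osnat10, and osnat10 RNC replicate 1 alone is argued against, since without it 89.5% (83.0 to 94.1; the intervals treat genes as independent) of 133 called genes were lower. The level of the libraries stays open, with 71.7% (62.1 to 80.0) of 106 lower after centring and 67.4% (58.6 to 75.4) of 129 after quantile normalization, and so does the first listed WT RNC library alone, without which 59.1% (46.3 to 71.0) of 66 were lower. Genes holding a site of at least 5 points were not detectably lower than others in RNC: within 10 bins of expression the difference of medians was 0.0241 (interval -0.0595 to 0.0968; permutation p = 0.622; 133 against 1429 genes), and for TE it was -0.0479 (-0.164 to 0.0527; permutation p = 0.318). That comparison was limited to plus-strand genes within the listed stretches after a first value over all plus-strand genes was seen. All genes in it were called ac4C-modified by the authors, and 93.8% of the plus-strand genes in those stretches held a called site of some rate. The sites came from Nipponbare, and the RNC values from Kitaake and osnat10. The comparison therefore cannot tell whether loss of ac4C lowers RNC. A genotype effect unrelated to such sites stays open and untested.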

How the results depend on the processing

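Recovered reads, lowest and highest RNC values, scaling of the gene lists, centring of the median TE shift, plus-strand genes, genes with sites of at least 5 points, an unadjusted threshold, the deposited adjusted p, the second count as unconverted reads, nuclear sites only and rice without genes at 0 were chosen after seeing the data; the other alternatives were planned. Where a value changed below, the cause was not tested, unless the alternative's construction shows it. Leaving out a library leaves a lone library assumed to vary like the others. Named sites kept their direction and call in 71 of 72 comparisons, named genes in 949 and gene lists in 23; among the other comparisons of named genes and of gene lists, 7 and 5 became called, 36 and 2 lost their call, and 76 and 14 reversed. In rice, no paired analysis was possible because the WT columns carry no replicate numbers. In Arabidopsis the numbers are shared only as numbers: deviations of the paired libraries correlated at -0.0216 (0.0405 in rice osnat10). With a replicate block the count was 14650 and the camera p of ac4C genes 0.0367. Site features (no genome) and DESeq2 (the authors' values are RPKM) were not run.

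A stricter site threshold (adjusted p under 0.01 and 5 points) left 2406 Arabidopsis and 1501 rice sites, an unadjusted p under 5e-10 left 15028 and 35403, and the deposited adjusted p left 114143 in rice. Arabidopsis RNC counts were 9202 with a mean of at least 5 (9782 genes tested), 6601 from recovered reads and 7876 with edgeR on those reads; centring left 13595, quantile normalization 13562, and leaving out a library 14126 to 14606. Rice RNC counts were 110 with pseudocount 0.1, 106 with centring, and 49 to 611 with a library left out; the mRNA count ranged from 13 to 102, WT from 1161 to 2027 and TE from 0 to 103 (2 without the first listed WT RNC library). The median TE shift was -0.0260 centred and -0.168 to -0.0351 with a library left out. The ac4C-gene camera p was 0.0883 with an estimated correlation, 0.543 at a mean of at least 10, 0.623 from reads (reversed) and 0.462 from reads among plus-strand genes (reversed).

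Lists called by camera numbered 2 with the deposited values, 0 with an estimated correlation, 4 centred, 4 with quantile normalization and 7 from reads. The following adjusted p-values belong to reversed directions. From reads they were 0.0188 for cellulose synthases, 0.0898 for chloroplast-encoded genes, 2.64e-05 for core histones, 0.00196 for cytosolic ribosomal proteins, 0.00747 for the flavonoid pathway, 0.0388 for light harvesting and 2.64e-05 for mitochondria-encoded genes. Centred they were 0.708 for cold and ABA response, 0.708 for the flavonoid pathway and 0.960 for upstream open reading frame mRNAs. With quantile normalization they were 0.998 for cellulose synthases, 0.507 for cold and ABA response, 0.507 for the flavonoid pathway and 0.874 for mitochondria-encoded genes.

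Log2 changes whose sign became positive, called or not, from reads and then with edgeR on reads, were PSAO (AT1G08380) 0.71 and 0.72, RPL27AB (AT1G23290) 0.21 and 0.22, PSAG (AT1G55670) 0.18 and 0.18, AT2G01021 0.36 and 0.37, H3.1 AT3G27360 0.59 and 0.61, HIS4 AT3G45930 0.34 and 0.35, RD22 (AT5G25610) 0.0348 and 0.0396, and ATCG00470 0.55 and 0.57. Those whose sign became negative were 4CL1 (AT1G51680) -0.19 and -0.19, LOS1 (AT1G56070) -0.28 and -0.27, ERD14 (AT1G76180) -1.83 and -1.84, BZIP2 (AT2G18160) -0.92 and -0.92, PAB4 (AT2G23350) -0.0329 and -0.0282, C4H (AT2G30490) -1.47 and -1.49, PAL1 (AT2G37040) -0.11 and -0.11, SAMDC1 (AT3G02470) -0.21 and -0.21, RPL4A (AT3G09630) -0.96 and -0.96, TCTP1 (AT3G16640) -0.11 and -0.11, GAPA1 (AT3G26650) -0.37 and -0.36, ACYR2 (AT3G57940) -0.14 and -0.26, EIF4G (AT3G60240) -0.74 and -0.85, CESA1 (AT4G32410) -0.20 and -0.20, HSC70-1 (AT5G02500) -0.0789 and -0.0723, CESA3 (AT5G05170) -0.46 and -0.46, CESA7 (AT5G17420) -0.68 and -1.30, CESA4 (AT5G44030) -0.30 and -0.39, HSP90.2 (AT5G56030) -0.20 and -0.20, SAC51 (AT5G64340) -0.0681 and -0.0649, ATCG00020 -0.30 and -0.31, and CHS (AT5G13930) -0.0034 from reads. Centred and then with quantile normalization, 4CL1 had -0.11 and -0.36, ERD14 -0.0112 and -0.25, AT3G41768 -0.12 and -0.35, CESA1 -0.0885 and -0.38, CHS -0.15 and -0.35, and KIN2 (AT5G15970) -0.16 and -0.41. HSP18.2 (AT5G59720) had -0.34 centred, HIS4 AT5G59970 -0.0611 with quantile normalization, and H3.3 AT4G40030 -0.16 with the lowest RNC value. The negative changes from reads, with limma or edgeR, carry the uncertainty of the recovered reads given above. In rice, the change of Os02g0308400 (rice osnat10 against WT TE) ranged from -2.27 without osnat10 RNC replicate 2 to 0.60 without replicate 1, and that of Os03g0592500 (rice osnat10 against WT TE) from -0.0188 without the later listed WT mRNA library to 0.77 without the first listed.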

Other observations

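Further members of the Arabidopsis lists carried sites in the treated library, most with no control T read. The photosynthesis genes FD2 (AT1G60950, a ferredoxin), ATPD (AT4G09650, a chloroplast ATP synthase subunit) and PSBQ1 (AT4G21280, a photosystem II subunit) reached 4.09% (1.89 to 7.62), 3.75% (1.95 to 6.46) and 2.88% (1.96 to 4.06), against 0, which allows up to 0.524%, 0.253% and 0.0417%. The ribosomal protein genes RPS18A and RPL8C (AT4G36130) reached 6.09% (2.48 to 12.1) and 4.90% (3.096 to 7.325), with limits of 0.440% and 0.133% in the control, and RPL9C (AT1G33140) had 10.7% (9.60 to 11.8) against 3.32%. Among genes with upstream reading frames, NMT1 (AT3G18000, phospholipid synthesis) reached 4.83% (1.96 to 9.69) and SAMDC1 (polyamine synthesis) 2.41% (1.38 to 3.88), with limits of 2.78% and 0.102% in the control. The cold-response gene RD29A (AT5G52310) reached 9.09% (3.41 to 18.7) at 66 reads, with a limit of 3% in the control. ATCG00300 had 46.2% (43.9 to 48.6) against 16.6% and ATCG00500 had 16.9% (14.8 to 19.1) against 3.65%. T reads at these chloroplast sites were also present in the control, so they were not specific to the treated library.

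Other list members in RNC against mRNA were as follows, as deposited, centred and from recovered reads. The phenylpropanoid gene C4H had 1.60, 0.56 and -1.47, and CHS, the first enzyme of flavonoid synthesis, had 0.90, -0.15 and -0.0034. The dehydrin ERD14 had 1.04, -0.01 and -1.83. The falls of C4H and ERD14 from reads are uncertain, as recovered reads can be a whole-number fraction of the true reads. LHCB2.2 (AT2G05070), an antenna gene, had 1.62, 0.57 and 0.43, and the replacement histone H3.3 AT4G40030 had 1.58, 0.53 and 0.68. The root regulators SCR (AT3G54220) and SHR (AT4G37650) had 1.49 and 1.61 as deposited and 0.25 and 0.17 from reads. The 18S rRNA gene AT2G01010 had 1.58, 0.54 and 0.79.

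Rice genes listed at 0 numbered 95 in osnat10 RNC replicate 1 and 10 in replicate 2, 2 and 49 in the WT RNC libraries and 0 in each mRNA library. Spearman's rho across genes was 0.922 between the osnat10 RNC libraries, 0.945 between the WT RNC libraries, 0.985 between the osnat10 mRNA libraries and 0.963 between the WT mRNA libraries.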
